A study of Homo sapiens with 18 samples.

How the data were processed

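Gene expression was measured by poly(A) mRNA sequencing in 18 libraries of A549 cells, an established human lung adenocarcinoma line. Per the labels, the libraries form 6 groups of 3 biological replicates. The groups are wild type (WT) untreated, WT given 100 µM hydrogen peroxide (H2O2) for 2 h, a stable S100A16 knockdown (KD) untreated, the S100A16 KD given 100 µM H2O2 for 2 h, a stable hnRNPM KD untreated and a stable MagoHB KD untreated. All controls were wild-type cells, and no line carrying only a vector is among the groups. The knockdown method is not given in the sources used here.

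The authors deposited whole-number read counts per gene for all 18 libraries, with the coordinates and exon length of each gene, and a table of RPKM values for the same genes. Per the submitters' processing notes, the tools were FastQC 0.11.9, HISAT2 2.2.1, SAMtools 1.15.1, StringTie 2.1.4 and DESeq2 1.32.0, with genome build GRCh38 (hg38). The program that made the counts, its annotation and whether it used strand are not given in the sources used here. Genes that overlap another gene, antisense genes and genes with near-identical copies are therefore uncertain. The deposited RPKM values equalled the counts divided by exon length in kilobases and by total counts, on the usual RPKM scale. This held for 100% of the 531539 values above 0 within a relative tolerance of 0.001. Of the counts from 1 to 19, only 18.6% to 22% per library were odd, so both mates of a read pair were probably counted, and a fit to halved counts was added as an alternative. Per-sample columns that were not used numbered 0.

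The count table held 44016 features. A symbol of GENCODE 29 matched 29098 of them, and 28618 overlapped the matched gene on GRCh38. Libraries were grouped by the labels alone. Counts were tested with edgeR 4.0.16 (R 4.3.3) by the robust quasi-likelihood F test, with TMM scaling, the filterByExpr filter over the 6 groups and 1 mean per group fitted over all 18 libraries. This kept 22382 genes, of which 17530 carried a current or older gene symbol. P-values were adjusted by Benjamini-Hochberg over all genes tested and called under 0.05, and genes with an absolute log2 fold change of 1 or more were counted as well. Every adjusted p of a gene below comes from this test unless another is named. Levels are CPM, scaled by TMM.

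The 7 comparisons were H2O2 in WT, H2O2 in the S100A16 KD, the S100A16 KD against WT without and under H2O2, the interaction of that KD with H2O2, and the hnRNPM and MagoHB KDs against untreated WT. Covariances of log2 fold changes between KDs were set beside 50 simulated draws with no change, since the KDs share the untreated WT libraries. In data simulated from the real means and library sizes, 66 or 67 genes with a mean of at least 5 CPM were changed at each fold size. Of genes changed 1.5-fold, 52.2% were recovered for the interaction, over 21826 genes. The other comparisons recovered from 80.6% (hnRNPM KD, over 21834 genes) to 98.5% (H2O2 in WT, over 21847 genes) at that size.

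Gene lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists with at least 5 tested members. Estimated correlations and fry were alternatives. Camera asks whether a list's genes moved more than the others, whereas fry asks whether they moved one way on balance, without comparing them with other genes. The lists covered NRF2 targets, other antioxidant enzymes, immediate early genes, p53 targets, heat shock genes, the endoplasmic reticulum unfolded protein response, the ATF4 integrated stress response, NF-kB and inflammatory genes, and interferon-stimulated genes. They also covered DNA replication, mitosis, epithelial, mesenchymal, YAP and TEAD target, hnRNP, SR protein, exon junction complex, nonsense-mediated decay, snoRNA host and S100 family genes. The remaining lists were glycolysis, hypoxia, cholesterol synthesis, nuclear oxidative phosphorylation (OXPHOS), mitochondrially encoded mRNAs, cytosolic ribosomal proteins, replication-dependent histones, alveolar type II and lung lineage genes, and markers of fibroblasts, leukocytes and endothelium. The endothelial list had only 4 tested members and was not tested.

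Genes were named by a fixed rule. It took the targeted gene and, among called genes with a symbol, the 10 highest and 10 lowest log2 fold changes. These needed a mean of at least 5 CPM and all 3 libraries of one group above all 3 of the other, which was not asked of the interaction. From each of up to 6 called lists with the smallest p, it took the 3 members with the smallest adjusted p in the list's direction and 1 in the other. Where fewer than 20 genes were called, all with a symbol were named. S100A14, S100A13, MAGOH and RBM8A were added for the KDs, and HMOX1 and TXNRD1 for H2O2. Of the genes named by the rule, 1 is not reported here. The design, gene lists, naming rule and most alternatives were fixed before the data were examined.

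The alternatives were DESeq2 size factors, total counts alone, no filter beyond 1 count, CPM of 5 or more in at least 3 libraries, the replicate number as a block, only the libraries of the groups compared, each library left out in turn, DESeq2 1.42.0, and limma on log2(RPKM + 1) and log2(RPKM + 0.1). The limma fits kept genes with an RPKM of 1 or more in at least 3 libraries, and log2(RPKM + 1) was also fitted to all genes above 0. Halved counts, a fit without 4 libraries, gene lists with only the groups compared and covariances with 1 library left out were added after seeing the data. Transcript usage and splicing were not analysed here, because the tables hold genes. Words of 7 bases in 3' UTRs were scanned over 9642 genes with GENCODE 29 transcripts, in a model with UTR length and GC content. Principal components used the 2000 most variable genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and the R package data.table, 1.17.8, were also used.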

Results

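Messenger RNA was counted in A549 cells that were wild type (WT) or carried a stable knockdown (KD) of S100A16, hnRNPM or MagoHB. S100A16 is a calcium-binding protein of the S100 family, hnRNPM is a nuclear RNA-binding protein that regulates splicing, and MagoHB is a core protein of the exon junction complex. The study's title concerns S100A16 and alternative splicing under oxidative stress. WT cells and the S100A16 KD were each measured untreated and after 2 h of 100 µM H2O2, and the other KDs untreated, with n = 3 libraries in each of 6 groups. Totals ranged from 36612997 counts (hnRNPM KD 2) to 51406431 (MagoHB KD 2). The counts are per gene, so changes in splicing within a gene were not analysed here.

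Each targeted mRNA was lowest in its own KD. S100A16 mRNA (GRCh38 chromosome 1, 153606886 to 153613145) was 119 ± 1.8 CPM in untreated WT and 8.43 ± 0.58 CPM in the untreated S100A16 KD (SD, n = 3), which is 7.11% of WT (log2 fold change -3.81, adjusted p = 6.82e-15). Under H2O2 it was 124 ± 5.5 CPM in WT and 6.93 ± 0.41 CPM in the KD, or 5.61% (adjusted p = 2.66e-15). HNRNPM (chromosome 19, 8444767 to 8489114) fell from 1770 ± 31 CPM to 368 ± 76 CPM in the hnRNPM KD, or 20.8% of WT (log2 -2.26, adjusted p = 2.59e-10). MAGOHB (chromosome 12, 10604190 to 10613623) fell from 150 ± 5.3 CPM to 52.1 ± 13 CPM in the MagoHB KD, or 34.8% (log2 -1.52, adjusted p = 3.08e-07). Its per-library values there were 61.6, 37.8 and 57 CPM.

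The targeted mRNAs also differed in KDs of the other genes. S100A16 mRNA fell to 51.2% of WT in the MagoHB KD (60.6 ± 11 CPM, adjusted p = 2.79e-07) and stood at 121 ± 16 CPM in the hnRNPM KD (adjusted p = 0.867). MAGOHB fell to 65% of WT in the untreated S100A16 KD (97.3 ± 2.9 CPM, adjusted p = 0.00122) and to 44.4% in the hnRNPM KD (66.4 ± 11 CPM, adjusted p = 3.68e-06). HNRNPM fell to 67.5% in the untreated S100A16 KD (1190 ± 32 CPM, adjusted p = 0.000911) and to 80.4% in the MagoHB KD (1420 ± 240 CPM, adjusted p = 0.0458). Its log2 changes there were -0.57 and -0.31, where total counts alone shift all values upward by 0.24 and 0.21. Its per-library values in the MagoHB KD were 1600, 1150 and 1510 CPM, lowest in MagoHB KD 2, a library that stood apart from its replicates. RBM8A, the exon junction partner of MAGO proteins, fell to 52.5% of WT in the untreated S100A16 KD (log2 -0.93, adjusted p = 4.38e-10), 74.4% in the hnRNPM KD (adjusted p = 2.88e-05) and 75% in the MagoHB KD (adjusted p = 5.12e-05). MAGOH, a near-identical copy of MAGOHB so that counts of the pair are uncertain, fell to 63.1% in the untreated S100A16 KD (adjusted p = 8.95e-07). Its log2 change was -0.12 in the hnRNPM KD (adjusted p = 0.231) and -0.13 in the MagoHB KD (adjusted p = 0.216), the latter 0.08 by total counts alone.

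The neighbours of S100A16 on chromosome 1 served as local controls. S100A14 (153614255 to 153616986) lay near the floor, at 0.492 ± 0.016 CPM in the untreated S100A16 KD and 0.486 ± 0.11 CPM in WT (adjusted p = 0.972). Its log2 change was -0.10 under H2O2 (adjusted p = 0.832), -0.26 in the hnRNPM KD (adjusted p = 0.575) and 0.13 in the MagoHB KD (adjusted p = 0.788). S100A13 (153618787 to 153631360) had a log2 change of -0.07 in the untreated S100A16 KD (adjusted p = 0.327) and of -0.02 under H2O2 (adjusted p = 0.787). By total counts alone it was called higher in both, at 0.17 (adjusted p = 0.0275; alternatives from 0.0223 to 0.785) and 0.16 (adjusted p = 0.0304; alternatives from 0.0218 to 1). The limma fits called it higher too. S100A13 rose by 0.18 in the hnRNPM KD (adjusted p = 0.0126), a call lost with no filter beyond 1 count (0.17, adjusted p = 0.0735). It fell by 0.33 in the MagoHB KD (adjusted p = 0.000111), where S100A13 was at -0.12 by total counts alone (adjusted p = 0.124, with alternatives for S100A13 in MagoHB KD cells from 4.95e-07 by the DESeq2 Wald test to 0.18).

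**Figure D1:**
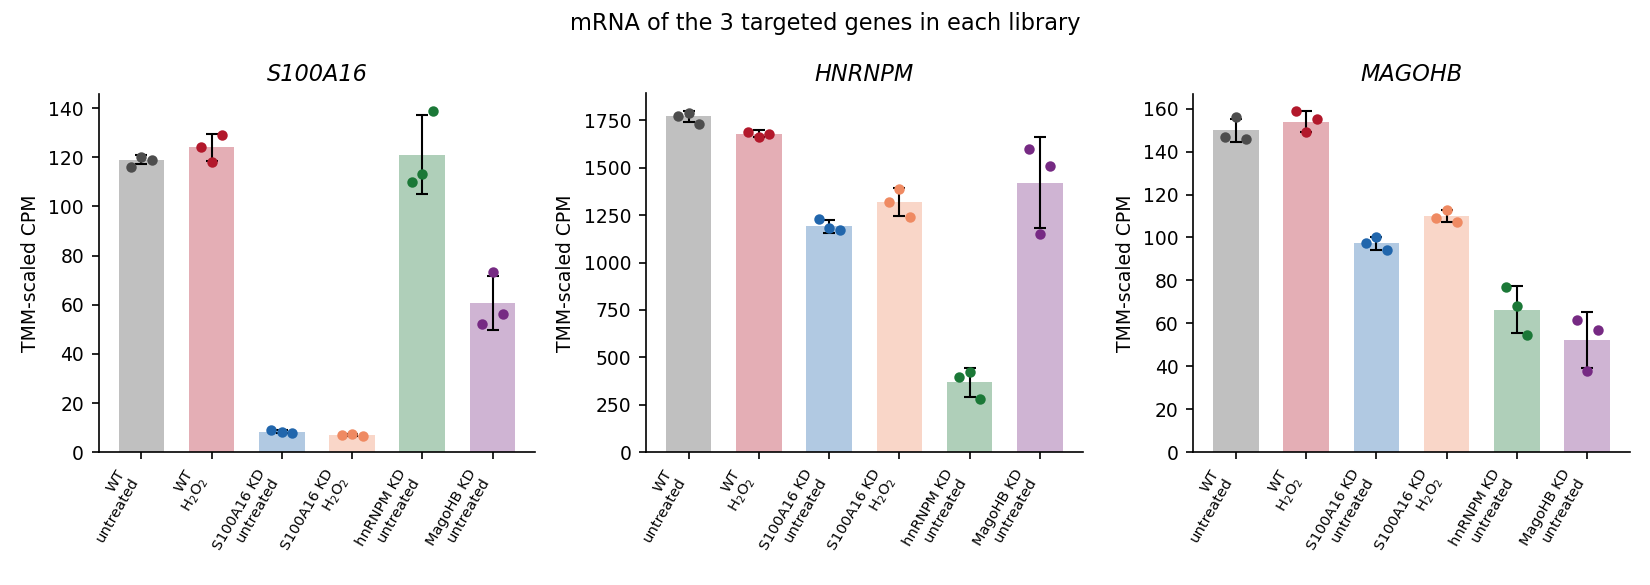
TMM-scaled CPM of S100A16, HNRNPM and MAGOHB in the 6 groups, with points for libraries, bars for means and error bars for SD (n = 3). S100A16 falls from 119 to 8.43 CPM in its untreated KD, HNRNPM from 1770 to 368 CPM and MAGOHB from 150 to 52.1 CPM.

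The first 3 principal components held 42.3%, 21.6% and 10.4% of the variance. WT libraries lay between 39.6 and 44.2 on the first component and S100A16 KD libraries between -33.3 and -29.6, with or without H2O2. Within groups, 3 libraries stood apart: S100A16 KD untreated 1, hnRNPM KD 3 and MagoHB KD 2. Their chi-square per degree of freedom against the other replicates was 16.8 to 36.5, against 1.62 to 3.01 for every other pair. Short structured RNAs made up 628 CPM in S100A16 KD untreated 1 and 37.5 to 75 CPM in the other libraries. Mitochondrial genes held 9.22% to 10.6% of counts in WT and hnRNPM KD libraries and 7.26% to 7.86% in S100A16 and MagoHB KD libraries.

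TMM factors were 0.908 to 0.932 in WT and 0.97 to 1.1 in the KDs. Scaling by total counts alone shifted all log2 fold changes upward by 0.24 in the untreated S100A16 KD, 0.18 under H2O2, 0.11 in the hnRNPM KD and 0.21 in the MagoHB KD. All changes below are relative to TMM scaling.

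**Figure D2:**
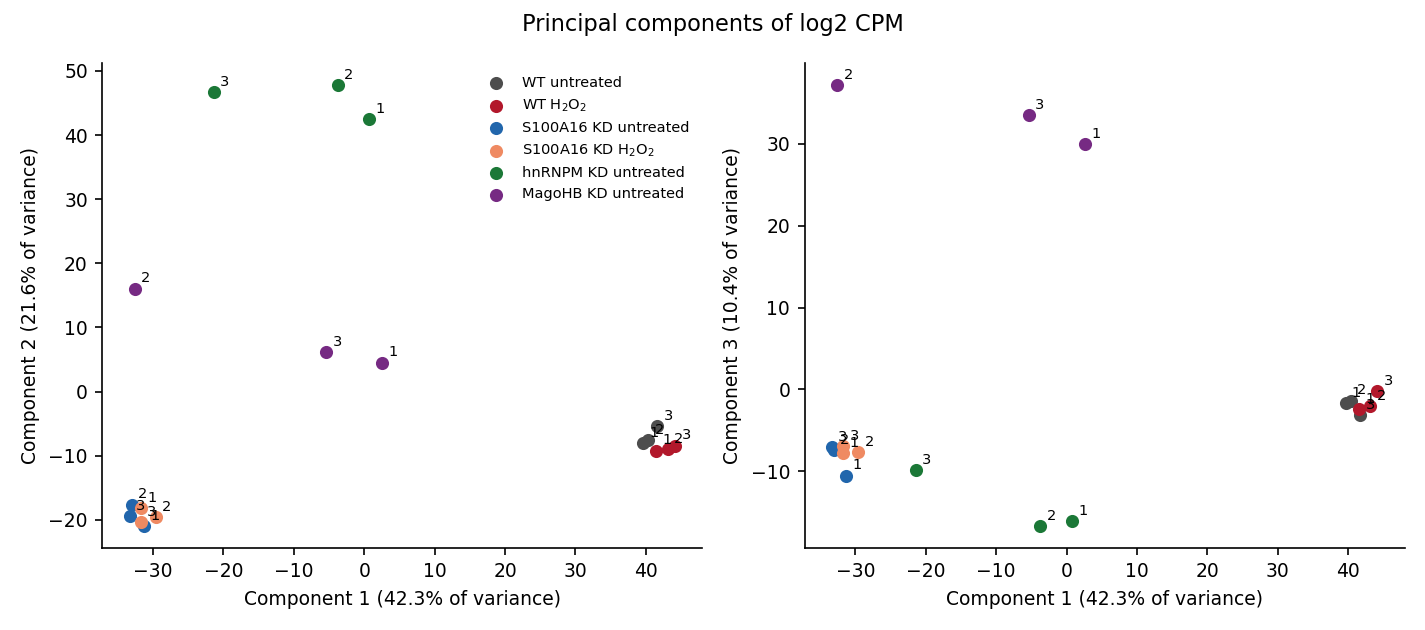
Principal components 1 and 2 (left) and 1 and 3 (right) of log2 CPM for the 18 libraries, coloured by group and numbered by replicate, with the share of variance on each axis. WT libraries lie at 39.6 to 44.2 on component 1, and MagoHB KD 2 lies at -32.6, apart from MagoHB KD 1 at 2.58 and 3 at -5.36.

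Treatment of WT cells with H2O2 for 2 h raised immediate early genes, the transcription factors and signalling regulators that respond first to stimuli. EGR1 rose 29.2-fold, from 1.64 ± 0.32 to 48 ± 4.9 CPM (SD, n = 3; log2 4.87, SE 0.30, adjusted p = 3.49e-07). FOS rose 10.5-fold, from 7.19 ± 0.37 to 75.8 ± 5.4 CPM (adjusted p = 2.09e-08), FOSB 8.51-fold (adjusted p = 8.58e-08) and the nuclear receptor NR4A1 6.00-fold (adjusted p = 1.1e-09). Smaller rises came from ZFP36 (log2 1.39), which promotes decay of AU-rich mRNAs, IER2 (1.31), the phosphatase DUSP1 (1.31, from 105 to 259 CPM), NR4A2 (1.19), KLF10 (0.95), CYR61 (0.93) and IER3 (0.88), with adjusted p from 8.58e-08 to 0.00296. The largest falls included the splicing-factor kinases CLK1 (log2 -0.78, from 80.9 ± 2.2 to 47.2 ± 1.8 CPM, adjusted p = 9.01e-08) and CLK4 (-0.64, adjusted p = 1.28e-06), and the phospholipid enzyme LPCAT4 (-0.60, adjusted p = 0.000107). Mitochondrial tRNA genes fell as well: MT-TW (log2 -0.95), MT-TY (-0.66), MT-TC (-0.65), MT-TT (-0.61), MT-TN (-0.60) and MT-TA (-0.45).

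The edgeR test called 50 genes with H2O2 in WT, of which 33 rose and 17 fell, and 13 rose and 1 fell at least 2-fold. At an unadjusted p under 0.05 there were 1477 genes. DESeq2 called 97, and a fit to the WT libraries alone called 535. The heme oxygenase gene HMOX1 (log2 0.05, adjusted p = 0.979) and the thioredoxin reductase gene TXNRD1 (0.04, adjusted p = 0.986), both NRF2 targets, did not pass the test.

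Of 32 immediate early genes, 15 rose and 0 fell with H2O2 in WT, and 24 rose when adjusted over the list alone (camera adjusted p = 3.03e-143, and adjusted p = 4.52e-05 with an estimated correlation). This was 1 of 2 list calls in all 7 comparisons that held with an estimated correlation, the other being the same list in the interaction. Of 25 NF-kB and inflammatory genes, 3 rose (5 adjusted over the list alone): the cytokine genes CXCL2 (log2 1.49, adjusted p = 0.0152) and LIF (0.27, adjusted p = 0.0338) and the prostaglandin synthase PTGS2 (0.77, adjusted p = 2.95e-06). That list was called at adjusted p = 2.44e-10, and at adjusted p = 0.284 with an estimated correlation. Of 13 mitochondrially encoded mRNAs, 3 fell (7 adjusted over the list alone), namely MT-ND6 (-0.47), MT-ND5 (-0.37) and MT-CYB (-0.27, adjusted p = 0.0178), with adjusted p = 0.112 for the list with an estimated correlation. The ribosomal protein list had a median of 0.11 with 0 of 55 genes called (4 rose adjusted over the list alone), and adjusted p = 0.154 with an estimated correlation. In the fit to WT libraries alone, 23 of those 55 rose.

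Another 8 lists were called in WT at the preset correlation and not with an estimated one. These were nuclear OXPHOS (0 of 39 genes called, adjusted p = 0.625 with an estimated correlation), YAP and TEAD targets (CYR61 and AMOTL2 of 21 rose, 4 adjusted over the list alone; adjusted p = 0.625), histones (0 of 12; adjusted p = 0.458) and SR protein factors (CLK1 and CLK4 of 28 fell; adjusted p = 0.659). The rest were nonsense-mediated decay (0 of 20; adjusted p = 0.112), the unfolded protein response (0 of 18; adjusted p = 0.193), snoRNA hosts (1 of 20 rose, 2 adjusted over the list alone; adjusted p = 0.193) and interferon-stimulated genes (0 of 42, 1 adjusted over the list alone; adjusted p = 0.906). The NRF2 target list (0 of 28; camera adjusted p = 0.0775) and the other antioxidant enzymes (0 of 21; camera adjusted p = 0.0898) were not called. The NRF2 list was called in 2 of 6 fits with 1 library left out. A fit to WT libraries alone called 4 of 28 NRF2 targets and 1 of 21 other antioxidant enzymes higher and 0 lower. CXCL2, LIF, MT-CYB and AMOTL2 lost their call in most fits with 1 library left out. The YAP, SR protein and nonsense-mediated decay calls ended without 1 WT H2O2 library, at adjusted p = 0.0533 (without 2), 0.0531 (without 2) and 0.115 (without 3). The unfolded protein response, snoRNA host and interferon calls ended in 2, 3 and 3 of 6 fits with 1 library left out, at up to 0.0717 and 0.109 (without WT H2O2 3) and 0.467 (without WT untreated 3).

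H2O2 in the S100A16 KD lowered 3 mitochondrial tRNA genes and raised 0 genes in the edgeR test over all 18 libraries. MT-TY fell from 143 ± 11 to 85.9 ± 5.9 CPM (SD, n = 3; log2 -0.73, adjusted p = 1.06e-05), as did MT-TC (-0.70, adjusted p = 1.06e-05) and MT-TN (-0.49, adjusted p = 0.000158). MT-TY and MT-TC overlap each other, and all 3 are encoded on the mitochondrial genome, so they may not be separate signals. EGR1 was 1.53 ± 0.41 CPM untreated and 3.20 ± 1.4 CPM with H2O2 (log2 1.05, adjusted p = 0.141, in a fit to the KD libraries alone), and FOS was 7.55 ± 0.24 and 11.3 ± 3.7 CPM (log2 0.57, adjusted p = 0.424). HMOX1 had a log2 change of 0.14 (adjusted p = 0.771) and TXNRD1 of 0.05 (adjusted p = 0.968). Genes at an unadjusted p under 0.05 numbered 1515, DESeq2 called 54 (40 higher, 14 lower), and the fit to the KD libraries alone called 804 (487 higher, 317 lower). Without S100A16 KD untreated 3, edgeR called 7.

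Camera called 13 lists with H2O2 in the S100A16 KD, all upward, and none held with an estimated correlation. The largest calls were ribosomal proteins (median 0.08, 0 of 55 genes called, list adjusted p = 5.14e-09, and adjusted p = 0.705 with an estimated correlation) and hnRNP genes (median 0.11, 0 of 30, list adjusted p = 9.74e-07, and adjusted p = 0.808 with an estimated correlation). The immediate early list had a median of 0.11 with 0 of 32 genes called, also adjusted over the list alone (list adjusted p = 0.00482, and adjusted p = 0.855 with an estimated correlation). The other 10 were nuclear OXPHOS, ATF4, SR protein, glycolysis, DNA replication, exon junction (median 0.03, or -0.01 by total counts alone), interferon, epithelial, snoRNA host and other antioxidant genes, at adjusted p from 0.489 to 0.929 with an estimated correlation. Leaving out 1 library ended 6 of them at highest adjusted p of 0.0564 (DNA replication, in 1 of 6 fits), 0.0655 (exon junction, 2), 0.26 (interferon, 2), 0.167 (epithelial, 4), 0.215 (snoRNA hosts, 3) and 0.169 (other antioxidant, 4). In the fit to the KD libraries alone, 9 of 30 hnRNP genes, 8 of 28 SR protein factors, 8 of 55 ribosomal protein genes and 4 of 32 immediate early genes rose.

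The interaction asked whether H2O2 acted differently in the S100A16 KD than in WT. The EGR1 change was lower in the KD (log2 interaction -3.81, SE 0.44, adjusted p = 0.00137). Interactions were also negative for FOS (-2.81, adjusted p = 2.74e-05), NR4A1 (-2.52, adjusted p = 3.16e-06), NR4A2 (-1.49, adjusted p = 0.00983), IER2 (-1.28, adjusted p = 9.48e-05), ZFP36 (-1.19, adjusted p = 0.0023), KLF10 (-0.84, adjusted p = 0.000892) and PTGS2 (-0.82, adjusted p = 0.000892). In the KD, NR4A2 stood at 6.74 ± 0.27 CPM untreated and 5.46 ± 0.75 CPM with H2O2 and PTGS2 at 21.8 ± 0.77 and 21.1 ± 0.97 CPM. CLK1, which fell in WT, had 63.8 ± 4.4 CPM untreated and 71.4 ± 1.6 CPM with H2O2 in the KD (interaction 0.94, adjusted p = 4.67e-06), and CLK4 had an interaction of 0.52 (adjusted p = 0.00775). The processed pseudogene EEF1A1P13, whose counts are uncertain for that reason, had an interaction of -0.65 (adjusted p = 0.00281). With limma on all genes above 0, ZFP36, KLF10, NR4A2 and EEF1A1P13 lost their call (each adjusted p = 0.0515). IER3 (-0.84, adjusted p = 0.0466), LIF (-0.44, adjusted p = 0.0194) and LPCAT4 (0.55, adjusted p = 0.0466) lost their call in most fits with 1 library left out, and NR4A2 in 4 of 12. HMOX1 (0.09) and TXNRD1 (0.01) both had an adjusted p of 1.

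In all, 21 genes passed the interaction test, 4 higher and 17 lower, with 1134 at an unadjusted p under 0.05, 35 called by DESeq2 and 261 in a fit to the 12 libraries of the 4 groups alone. Of 32 immediate early genes, 10 were lower and 0 higher (18 adjusted over the list alone; list adjusted p = 3.37e-71, and adjusted p = 0.00149 with an estimated correlation). The interaction's other 5 list calls were lost with an estimated correlation. They were mitochondrially encoded mRNAs (0 of 13 called, 3 higher adjusted over the list alone; adjusted p = 0.447), SR protein factors (2 of 28 higher; adjusted p = 0.530), NF-kB genes (2 of 25 lower, 4 adjusted over the list alone; adjusted p = 0.618), histones (0 of 12; adjusted p = 0.447) and hnRNP genes (0 of 30; adjusted p = 0.958). The edgeR count was 13 without WT untreated 3.

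**Figure D3:**
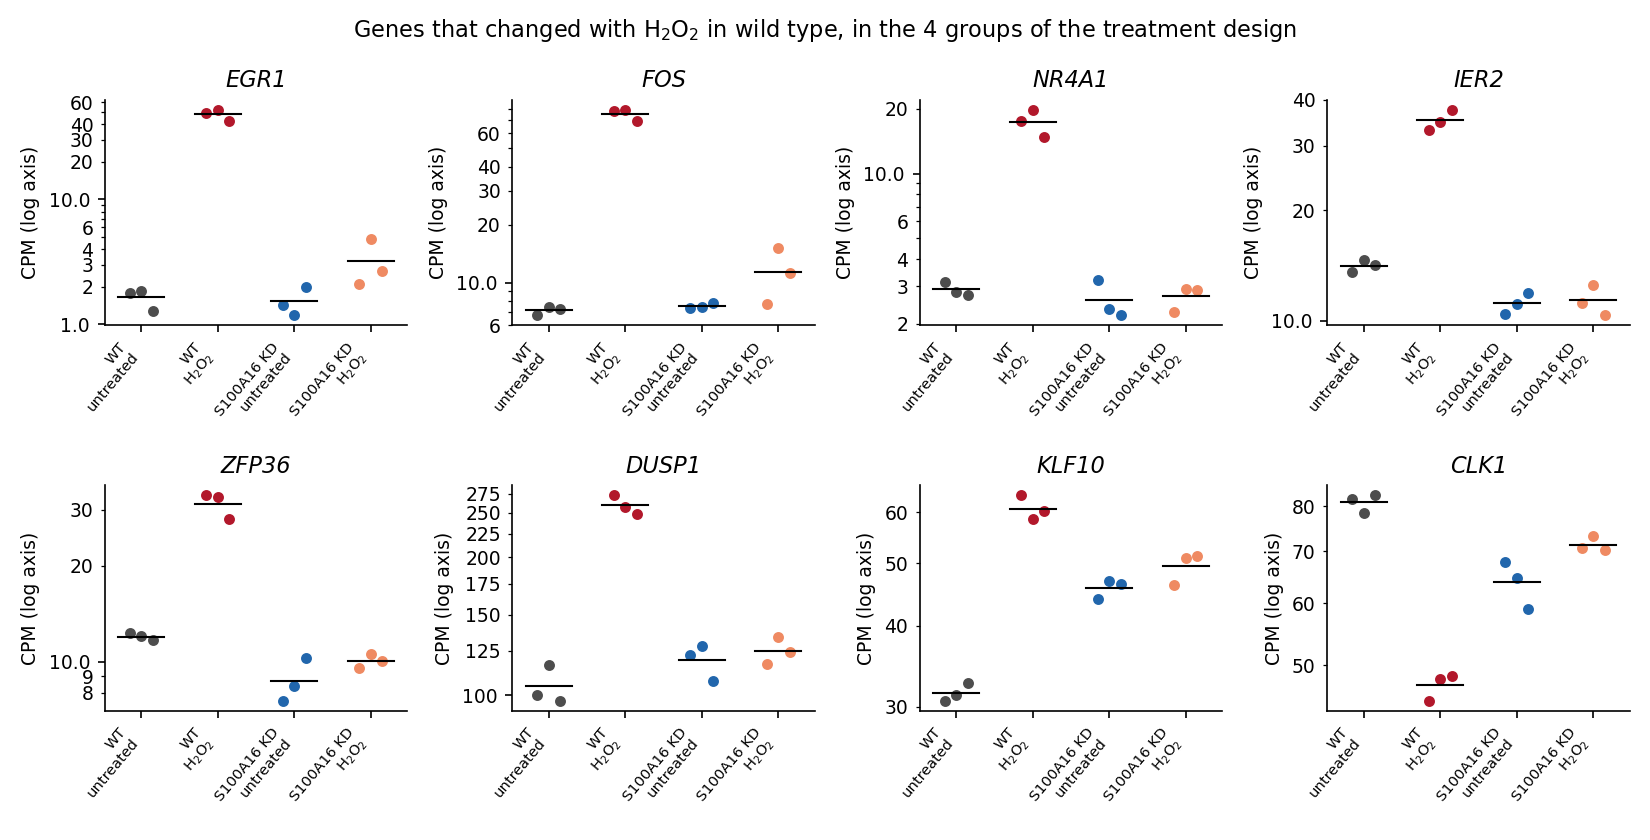
CPM on a log axis of EGR1, FOS, NR4A1, IER2, ZFP36, DUSP1, KLF10 and CLK1 in WT and S100A16 KD libraries with and without H2O2, with points for libraries and lines for means (n = 3). With H2O2, EGR1 rises from 1.64 to 48 CPM in WT and stands at 1.53 and 3.20 CPM in the KD.

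The untreated S100A16 KD was compared with untreated WT. TNFSF14, a TNF-family cytokine, rose 72.6-fold, from 0.867 ± 0.19 to 63.1 ± 4.1 CPM (SD, n = 3; log2 6.18, SE 0.56, adjusted p = 1.03e-06). OLR1, a receptor for oxidised lipoprotein, rose by 3.96, and the interferon-inducible XAF1, GBP3 and RSAD2 by 3.95, 3.76 and 3.49 on the log2 scale. The esterase CES1 fell from 17.9 ± 0.64 to 0.362 ± 0.059 CPM (log2 -5.62, adjusted p = 7.94e-12), as did the imprinted RNA H19 (-3.56), the phosphatase 2A catalytic gene PPP2CA (-3.20, from 167 to 18.2 CPM) with the overlapping MIR3661 (-3.47), C2orf48 (-3.03), the PCNA-binding KIAA0101 (-2.86), caveolin CAV1 (-2.71, from 214 to 32.8 CPM), CHCHD5 (-2.70) and PBDC1 (-2.68). Among the 10 genes named for their rises, 5 were short RNA genes: RNA5SP149 (5.61), RN7SL5P (4.59), RN7SK (4.27), RNA5-8S5 (3.83) and RN7SL2 (3.55). Their SD exceeded their mean, and without S100A16 KD untreated 1 RN7SK was at 1.78 (adjusted p = 0.142; alternatives from 0.000127), RN7SL2 at 0.40 (adjusted p = 0.303; alternatives from 0.00264 to 0.367) and RNA5SP149 at 3.27 (adjusted p = 0.0505; alternatives from 1.16e-05 to 0.0891). Without that library, RN7SL5P in S100A16 KD untreated was 1.24 (adjusted p = 0.00313; alternatives from 0.00016 to 0.145) and RNA5-8S5 in S100A16 KD untreated was 1 and kept its call (adjusted p over alternatives from 2.74e-05 to 0.151). Both lost their call with only the groups compared, RNA5-8S5 also with limma on all genes above 0.

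The edgeR test called 11713 genes in the untreated S100A16 KD (52.3% of those tested), with 6168 higher and 5545 lower, and 2458 higher and 872 lower at least 2-fold. Of the called genes, 52.7% were higher under TMM and 74% by total counts alone. Interferon-stimulated genes rose in 40 of 42 cases and fell in 0 (median 1.63, list adjusted p = 1.95e-26, and adjusted p = 0.241 with an estimated correlation), including PARP9 (1.80), the immunoproteasome gene PSMB8 (1.73) and IFI44L (2.99). Of 55 ribosomal protein genes, 54 fell and 0 rose (median -0.58, list adjusted p = 1.46e-29, and adjusted p = 0.0970 with an estimated correlation), among them RPS2 (-1.25, from 900 ± 8.0 to 378 ± 8.5 CPM), RPL24 (-1.01) and RPL12 (-0.83). Cholesterol synthesis genes fell in 20 of 24 cases and rose in 1 (list adjusted p = 5.69e-12, and adjusted p = 0.337 with an estimated correlation). They included the master regulator SREBF2 (-1.24) and the enzymes FDPS (-1.36) and MVK (-1.15), while the sterol carrier STARD4 rose by 0.56.

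Cell cycle and energy lists were also called downward in the untreated S100A16 KD, and none held with an estimated correlation (each adjusted p = 0.387). DNA replication genes fell in 34 of 36 cases and rose in 1 (list adjusted p = 4.38e-11, and adjusted p = 0.387 with an estimated correlation), with UNG at -1.32, CDC6 at -1.05, TIPIN at -0.61 and the cyclin CCNE1 higher by 0.44. Of 35 mitosis genes, 33 fell and 0 rose (list adjusted p = 3.85e-09, and adjusted p = 0.387 with an estimated correlation), including AURKA (-2.42, from 72.7 ± 1.4 to 13.6 ± 0.36 CPM), the cyclin CCNA2 (-1.60) and CDC25C (-0.77). Nuclear OXPHOS genes fell in 32 of 39 cases, or 33 adjusted over the list alone (list adjusted p = 6.1e-09, and adjusted p = 0.387 with an estimated correlation), with COX8A at -1.65, UQCRC1 at -1.09 and SDHC at -0.77. By total counts alone, 21 of the OXPHOS genes fell and 3 rose. All 13 mitochondrially encoded mRNAs fell, or 8 by total counts alone (adjusted p = 0.387 with an estimated correlation), in libraries whose mitochondrial share was lower.

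Splicing and stress lists were called in the untreated S100A16 KD as well, and none held with an estimated correlation. Among splicing and RNA factors, 15 of 18 exon junction complex genes, 20 of 28 SR protein factors (3 rose) and 24 of 30 hnRNP genes (3 rose) fell, at adjusted p of 0.387, 0.387 and 0.466 with an estimated correlation. By total counts alone, 10 fell and 3 rose of the exon junction genes, 14 and 7 of the SR protein factors and 20 and 5 of the hnRNP genes. Nonsense-mediated decay factors fell in 10 of 20 cases and rose in 3, with a median of -0.17 that turned to 0.07 by total counts alone (adjusted p = 0.0970 with an estimated correlation), and 12 of 20 snoRNA hosts fell and 4 rose, or 8 and 7 by total counts alone (adjusted p = 0.263 with an estimated correlation). NRF2 targets fell in 21 of 28 cases and rose in 4, and heat shock genes fell in 15 of 20 and rose in 3, both at adjusted p = 0.387 with an estimated correlation. NF-kB genes rose in 19 of 25 cases, YAP and TEAD targets in 15 of 21 and p53 targets in 19 of 28, at adjusted p of 0.387, 0.387 and 0.683 with an estimated correlation. Glycolysis genes fell in 11 of 19 cases and rose in 5, or 8 and 8 by total counts alone (list adjusted p = 0.0474, lost in 3 of 6 fits with 1 library left out, at up to 0.0644 without S100A16 KD untreated 1, and adjusted p = 0.387 with an estimated correlation). The mesenchymal (15 rose, 4 fell of 30; camera adjusted p = 0.0554), immediate early (13 rose, 3 fell of 32; 0.126) and epithelial lists (9 rose, 4 fell of 25; 0.145) were not called. Nor were hypoxia (8 rose, 4 fell of 24), unfolded protein response (8 rose, 6 fell of 18), ATF4 (7 rose, 11 fell of 27), other antioxidant (5 rose, 7 fell of 21), histone (3 rose, 2 fell of 12), lung lineage (6 rose, 2 fell of 11), fibroblast (1 rose, 2 fell of 10), leukocyte (2 rose of 8) and S100 family genes (2 fell of 12, the median of 0.02 against a mean of -0.09). By total counts alone, 11 rose and 4 fell of the ATF4 genes, 11 and 1 of the unfolded protein response, 10 and 7 of the other antioxidant and 3 and 2 of the S100 family genes. Endothelial markers, with 4 genes, were not tested as a list.

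The S100A16 KD and WT were also compared under H2O2. TNFSF14 rose by 5.86, OLR1 by 4.06, GBP3 by 3.66, XAF1 by 3.61 and RSAD2 by 3.44 on the log2 scale, followed by STMN3 (3.36), C14orf105 (3.33), IGFBP1 (3.21), TCHH (3.11) and UBD (3.08), with adjusted p up to 3.82e-05. Besides S100A16 itself (-4.16), genes that fell included CES1 (-5.79), EGR1 (-3.91, from 48 ± 4.9 to 3.20 ± 1.4 CPM; SD, n = 3; adjusted p = 2.12e-08), H19 (-3.41), MIR3661 (-3.41), PPP2CA (-3.03), CAV1 (-2.83), the mitochondrial import gene TOMM5 (-2.78), FOS (-2.74) and NR4A1 (-2.69). MAGOH (-0.56, adjusted p = 8.32e-06) and RBM8A (-0.93, adjusted p = 4.36e-10) fell as well. The edgeR test called 11759 genes (52.5%), 6241 higher and 5518 lower, so that 53.1% of called genes were higher under TMM and 70% by total counts alone.

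Of 32 immediate early genes, 15 were lower and 3 higher in the KD under H2O2 (list adjusted p = 0.000249, and adjusted p = 0.536 with an estimated correlation). All 55 ribosomal protein genes fell (list adjusted p = 4.17e-33, and adjusted p = 0.0773 with an estimated correlation), including RPS2 (-1.09), RPL32 (-0.97) and RPL34 (-0.85). Interferon genes rose in 40 of 42 cases (adjusted p = 0.218 with an estimated correlation), with PSMB8 at 1.89, PARP9 at 1.73 and IFI44L at 2.98. Cholesterol synthesis genes fell in 21 of 24 cases (adjusted p = 0.294 with an estimated correlation), with INSIG1 at -2.46, FDPS at -1.31, SREBF2 at -1.16 and STARD4 higher by 0.51. DNA replication (34 of 36; UNG -1.22, CDC6 -1.03, TIPIN -0.62, CCNE1 0.72), mitosis (31 of 35; AURKA -2.29, CCNA2 -1.55, CDC25C -0.94) and nuclear OXPHOS genes (35 of 39; COX8A -1.72, UQCRC1 -1, SDHC -0.85) fell, each at adjusted p = 0.536 with an estimated correlation. Of the 18 lists called, the other 11 were NRF2, exon junction, heat shock, YAP, hnRNP, mitochondrial mRNA, snoRNA host, NF-kB, SR protein, nonsense-mediated decay and mesenchymal genes, at adjusted p from 0.218 to 0.613 with an estimated correlation. The p53 (camera adjusted p = 0.0517) and glycolysis lists (0.113), called untreated, were not called here. Their medians were close, at 0.65 and -0.36 untreated and 0.68 and -0.32 under H2O2, and neither list was called in the interaction. The p53 list was called here in 2 of 6 fits with 1 library left out. The immediate early and mesenchymal lists were not called untreated, though the mesenchymal list was called untreated in 2 of 6 fits with 1 library left out. The median of the nonsense-mediated decay list, -0.14, turned to 0.05 by total counts alone.

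In the hnRNPM KD, the collagen gene COL21A1 and the cytokine gene IL11 had the largest rises among named genes. COL21A1 rose 40.1-fold, from 0.259 ± 0.071 to 10.5 ± 1.1 CPM (SD, n = 3; log2 5.33, SE 0.30, adjusted p = 4.3e-12). IL11 rose by 5.12 (from 0.615 to 21.5 ± 2.7 CPM), the activin antagonist FST by 4.29, NEK10 by 4.07, the pentraxin PTX3 by 4.00, the growth factor HBEGF by 3.31, the imprinted RNA MEG3 by 3.25, APLN by 3.24 and MYPN by 3.23. CES1 (-4.64), TM4SF20 (-3.93), VAV3 (-3.92), the 14-3-3 gene YWHAH (-3.76, from 110 ± 3.5 to 8.10 ± 0.59 CPM, adjusted p = 2.42e-19), MRPS33 (-3.43), TMEM19 (-3.00), F7 (-2.93) and CPNE3 (-2.88) fell. The aldo-keto reductases AKR1C2 (6190 ± 110 to 557 ± 160 CPM, log2 -3.47) and AKR1C1 (log2 -3.10) fell too, and their counts are uncertain because the family's sequences are near-identical.

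The test called 10999 genes in the hnRNPM KD (49.1%), 5676 higher and 5323 lower, and 1969 higher and 1240 lower at least 2-fold. Higher genes were 51.6% of those called under TMM and 63.1% by total counts alone. Of 28 NRF2 targets, 26 fell and 1 rose (list adjusted p = 9.68e-31, and adjusted p = 0.0814 with an estimated correlation), including TXNRD1 (-1.79, from 2440 ± 79 to 706 ± 57 CPM), the epoxide hydrolase EPHX1 (-1.89) and AKR1C3 (-2.14), while HMOX1 rose by 0.26. DNA replication genes fell in 28 of 36 cases and rose in 1 (29 fell adjusted over the list alone; adjusted p = 0.590 with an estimated correlation), with CCNE1 at -1.77, RFC4 at -1.56, CDC6 at -1.39 and CCNE2 at 0.30. Mitosis genes fell in 32 of 35 cases (33 adjusted over the list alone; adjusted p = 0.590 with an estimated correlation), with ANLN at -2.04, TTK at -1.37 and CCNA2 at -1.30. Heat shock genes fell in 17 of 20 cases and rose in 1 (adjusted p = 0.462 with an estimated correlation), with HSP90AA1 at -1.26, DNAJB1 at -0.80, AHSA1 at -0.64 and HSPA4L at 0.16. YAP and TEAD targets rose in 13 of 21 cases and fell in 3 (adjusted p = 0.573 with an estimated correlation), with the coagulation initiator F3 at 3.11, AMOTL2 at 0.97, WWC1 at 0.79 and LATS2 at -0.72. Nuclear OXPHOS genes fell in 24 of 39 cases (adjusted p = 0.636 with an estimated correlation), with the succinate dehydrogenase genes SDHD at -2.38 and SDHB at -2.27 and ATP5F1 at -0.84.

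Another 9 lists were called in the hnRNPM KD. Mesenchymal (18 rose, 1 fell of 30; 2 fell adjusted over the list alone), immediate early (19 rose, 3 fell of 32) and NF-kB genes (16 rose, 3 fell of 25; 18 rose adjusted over the list alone) moved upward, at adjusted p of 0.590, 0.590 and 0.654 with an estimated correlation. ATF4 (16 fell, 2 rose of 27; 17 fell adjusted over the list alone), cholesterol (16 fell, 1 rose of 24), glycolysis (13 fell, 4 rose of 19), other antioxidant (10 fell, 3 rose of 21), S100 family (6 fell, 1 rose of 12) and hnRNP genes (18 fell, 4 rose of 30; 19 fell adjusted over the list alone) moved downward, at adjusted p from 0.462 to 0.786 with an estimated correlation. The hnRNP list holds the targeted gene HNRNPM itself (log2 -2.26), whose fall follows from the knockdown. That list's call ended without hnRNPM KD 3, a library that stood apart (adjusted p = 0.0712). CCNE2 and HSPA4L lost their call in most fits with 1 library left out.

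The MagoHB KD was compared with untreated WT. The collagen gene COL5A3 rose 15.5-fold, from 2.83 ± 0.70 to 43.9 ± 19 CPM (SD, n = 3; log2 3.96, SE 0.40, adjusted p = 3.24e-06). FAM129A (3.87), RSAD2 (3.76), KLHDC7A (3.35), the insulin-like growth factor binder IGFBP3 (3.34), the keratin KRT17 (3.34), TRAF1 (3.04), MEG3 (2.98), ABCA12 (2.97) and TCHH (2.82) followed. MagoHB KD 2, which stood apart, had the highest values of several of these, as in FAM129A at 4.65, 24.6 and 5.98 CPM. Without it the log2 rise of FAM129A in MagoHB KD cells was 2.72, that of RSAD2 3.05, TRAF1 2.21, MEG3 2.33 and ABCA12 2.31. All 5 kept their call. CES1 (-4.02), TMEM245 (-2.82, from 58.0 ± 1.2 to 8.20 ± 0.31 CPM, adjusted p = 2.23e-17), PALM3 (-2.72), ST6GAL2 (-2.63), the sterol enzyme MSMO1 (-2.63), CMTM4 (-2.47), C2orf48 (-2.46), EFR3A (-2.44), the collagen lysyl hydroxylase PLOD2 (-2.43) and the protein degradation gene SEL1L (-2.35) fell.

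The test called 10193 genes in the MagoHB KD (45.5%), 5208 higher and 4985 lower, and 1875 higher and 693 lower at least 2-fold. Higher genes were 51.1% of those called under TMM and 74.7% by total counts alone. Cholesterol synthesis genes fell in 22 of 24 cases and rose in 0 (1 rose adjusted over the list alone; adjusted p = 0.355 with an estimated correlation), with MVD at -1.27 and NSDHL at -1.09. Of 13 mitochondrially encoded mRNAs, 12 fell (adjusted p = 0.234 with an estimated correlation), including MT-CYB (-0.96), MT-CO3 (-0.98) and MT-ATP6 (-0.86). Ribosomal protein genes rose in 43 of 55 cases and fell in 0 (46 rose adjusted over the list alone; median 0.26; adjusted p = 0.380 with an estimated correlation), with RPL28 at 0.62, RPL12 at 0.59 and RPS12 at 0.58. Interferon genes rose in 33 of 42 cases and fell in 1 (34 rose adjusted over the list alone; adjusted p = 0.609 with an estimated correlation), with HERC6 2.5-fold and PSMB9 2.38-fold higher, USP18 at 0.63 and the antiviral gene OAS1 at -1.02. Mitosis genes fell in 30 of 35 cases (32 adjusted over the list alone; adjusted p = 0.694 with an estimated correlation), with AURKA at -1.36, ANLN at -0.96 and ECT2 at -0.60. Heat shock genes fell in 17 of 20 cases (18 adjusted over the list alone, and adjusted p = 0.380 with an estimated correlation), with CHORDC1 at -1.41, HSPA4L at -1.35 and BAG3 at -0.70, while the small chaperone CRYAB rose by 2.46. By total counts alone, 9 of the heat shock genes fell and 2 rose.

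Another 10 lists were called in the MagoHB KD. YAP and TEAD (14 rose, 6 fell of 21), NF-kB (17 rose, 3 fell of 25), immediate early (17 rose, 2 fell of 32), p53 (16 rose, 2 fell of 28; 17 rose adjusted over the list alone) and snoRNA host genes (12 rose, 2 fell of 20) moved upward, at adjusted p from 0.234 to 0.734 with an estimated correlation. NRF2 targets (20 fell, 3 rose of 28), DNA replication genes (12 of 36 fell, 7 adjusted over the list alone, but 6 fell and 1 rose by total counts alone) and SR protein factors (13 of 28 fell and 0 rose, but 6 fell and 9 rose by total counts alone) moved downward, at adjusted p from 0.609 to 0.734 with an estimated correlation. The unfolded protein response list (8 fell, 4 rose of 18; adjusted p = 0.234 with an estimated correlation) and nuclear OXPHOS genes (18 fell, 2 rose of 39; 19 fell adjusted over the list alone; adjusted p = 0.734 with an estimated correlation) had medians of -0.12 and -0.19 that turned to 0.09 and 0.01 by total counts alone. Without MagoHB KD 2, which stood apart, the OXPHOS (adjusted p = 0.134), p53 (0.115), DNA replication (0.337) and SR protein calls (0.101) ended.

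The 3 KDs were then compared with one another. Across 22382 genes, the covariance of log2 fold changes was 0.413 for the S100A16 and hnRNPM KDs, 0.437 for the S100A16 and MagoHB KDs and 0.412 for the hnRNPM and MagoHB KDs. Among genes at 5 CPM or more in at least 3 libraries they were 0.221, 0.211 and 0.199. With no effects and the same shared WT libraries, 50 simulated draws gave 0.0493 to 0.0495 (r 0.501 to 0.510 across genes, against an observed r of 0.539, 0.628 and 0.581). With no library shared, by use of the S100A16 contrast under H2O2, the covariances were 0.35 with the hnRNPM KD and 0.367 with the MagoHB KD. Genes called in all 3 KDs in the same direction numbered 3784, with 1946 higher and 1838 lower. For the S100A16 and hnRNPM KDs, 3160 genes were higher in both and 2779 lower in both, where independent lists would share 1564 and 1319. The shared WT libraries can add to that overlap. With no library shared, by use of the S100A16 contrast under H2O2, 3063 were higher and 2691 lower in both, against 1583 and 1312. Genes are not independent replicates, and these counts do not separate effects of the targeted genes from what the KD lines share against WT.

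Direct contrasts showed where the KDs differed. These contrasts were not among the comparisons listed for the design that was fixed before the data were examined. Fits with a library left out, a replicate block or other scaling were not run for them. The libraries that stood apart, MagoHB KD 2 among them, were kept, so how far the list calls below depend on them was not tested. The direct contrasts called 10029 genes between the S100A16 and MagoHB KDs, 10931 between the S100A16 and hnRNPM KDs and 9963 between the hnRNPM and MagoHB KDs. The S100A16 KD was below the MagoHB KD in all 55 ribosomal protein genes (median -0.81, adjusted p = 0.00468 with an estimated correlation) and in 15 of 20 snoRNA hosts (adjusted p = 0.00738 with an estimated correlation). It was below it in 11 of 20 nonsense-mediated decay factors and above it in 3 (adjusted p = 0.0210 with an estimated correlation), and above it in 11 of 18 unfolded protein response genes and below it in 4 (adjusted p = 0.0409 with an estimated correlation). Against the hnRNPM KD, the S100A16 KD was lower in 55 of 55 ribosomal protein genes (adjusted p = 0.0668 with an estimated correlation), and higher in 40 of 42 interferon genes and 25 of 28 NRF2 targets (both adjusted p = 0.293 with an estimated correlation). The hnRNPM KD was below the MagoHB KD in 25 of 28 NRF2 targets and above it in all 13 mitochondrially encoded mRNAs (both adjusted p = 0.214 with an estimated correlation).

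**Figure D4:**
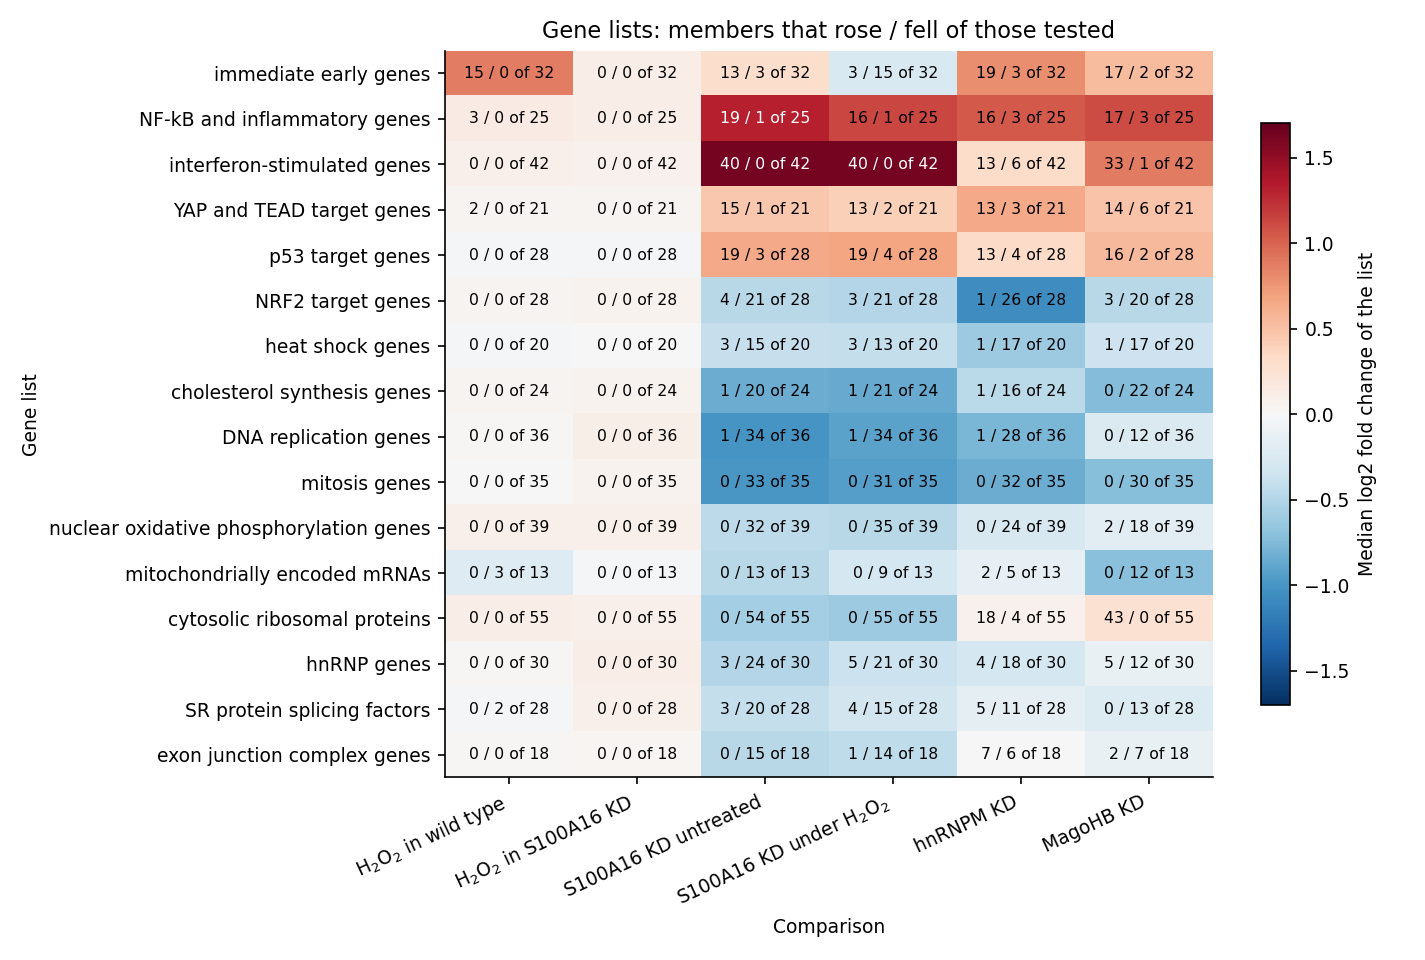
Median log2 fold change under TMM (colour) of 16 gene lists in 6 comparisons, with the number of members that rose and fell of those tested in each cell. Ribosomal protein genes fall in 54 of 55 cases in the untreated S100A16 KD and rise in 43 of 55 in the MagoHB KD, where the OXPHOS, hnRNP and exon junction medians of -0.19, -0.13 and -0.12 turn to 0.01, 0.08 and 0.08 by total counts alone.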

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

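The tests of exposure and of a raised baseline were chosen only after the result was seen, and the splits, the interaction and the fits with 1 library left out were not. The response to H2O2 differed between WT and S100A16 KD cells by the interaction term in 21 genes and 6 gene lists, of which 1, the immediate early list, held with an estimated correlation. The log2 interaction was -3.81 for EGR1, -2.81 for FOS, -2.52 for NR4A1, -1.49 for NR4A2, -1.28 for IER2, -1.19 for ZFP36, -0.84 for IER3, -0.84 for KLF10, -0.82 for PTGS2, -0.65 for EEF1A1P13 and -0.44 for LIF. It was 0.94 for CLK1, 0.55 for LPCAT4 and 0.52 for CLK4. Of 100 splits of the 12 libraries, 7 called at least 21 genes, the real one included, and the highest of the others called 28, so the count alone does not exclude chance. The 6 other such splits all kept the WT libraries grouped as labelled, and the 90 splits that did not called at most 0 genes, so these counts follow the WT response.

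The 15 immediate early genes called with H2O2 in WT had a median rise of 1.31 (log2), against 0.11 in the S100A16 KD. A missing exposure of the KD libraries is argued against, though weakly, by the 35 other genes called in WT. Of these, 80% (28) moved the same way in the KD (exact binomial p = 0.000508, though genes are not independent). The 35 include several mitochondrial tRNA genes, of which MT-TY and MT-TC overlap. All of these tRNA genes are encoded on the mitochondrial genome, so they may not be separate signals. In fits to the groups compared the share was 68.2% of 535 genes, 26 of them immediate early genes, and r across all genes was -0.000247. A baseline already raised in untreated KD cells is argued against for the 15 immediate early genes as a set, under TMM. Their median difference from WT was 0.09 (SE over the genes 0.11), 6.99% of the rise. Total counts alone shift this contrast upward by 0.24. Over all 32 list members the median was 0.30 under TMM, with 13 called higher and 3 lower, and 0.53 by total counts alone. That 1 library decides is argued against by the list's call in 12 of 12 fits with 1 library left out (highest adjusted p = 4.91e-60). A weaker or differently timed response of the KD line stays open as a hypothesis, and a cause in S100A16 itself cannot be told from other differences of a single line, since 1 time point and no vector control were analysed here.

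With H2O2 in WT, 50 genes were called and the highest of the other splits gave 0. In the S100A16 KD the values were 3 and 0. For the untreated KDs they were 11713 and 0 (S100A16), 10999 and 0 (hnRNPM) and 10193 and 1 (MagoHB), and for the S100A16 KD under H2O2 11759 and 0. Each of these has 10 splits, of which 1 (the real one) gave as many genes, and 10 splits are too few for a share under 0.05.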

How the results depend on the processing

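Halved counts, the fit without 4 libraries, gene lists with only the groups compared and covariances with 1 library left out were chosen only after the result was seen. The 4 were S100A16 KD untreated 1, hnRNPM KD 3 and MagoHB KD 2, which stood apart, and WT H2O2 3, which did not (chi-square per degree of freedom 2.72 and 2.91). Each targeted mRNA passed its tests in its own KD under all alternatives. Falls of these mRNAs in KDs of the other genes were not part of that check. Of 229 values of named genes, 227 kept direction and call with DESeq2 size factors, 226 of 227 with the DESeq2 test, 220 by total counts alone (5 turned), 224 with no filter, 215 of 220 at 5 CPM, 221 with only the groups compared, 227 with halved counts, 227 without the 4 libraries, 216 of 224 with each limma fit and 213 with limma on all genes above 0. Of 1470 values with 1 library left out, 1393 kept both, 71 lost their call and 6 turned.

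Called lists numbered 1, 0, 0, 0, 1, 0 and 0 with estimated correlation (H2O2 in WT, S100A16 KD untreated, H2O2 in the S100A16 KD, S100A16 KD under H2O2, interaction, hnRNPM KD, MagoHB KD). By fry they numbered 5 with H2O2 in WT, 1 with H2O2 in the KD, 1 in the interaction and 23 in the hnRNPM KD. Interaction lists were 10 without the 4 libraries and 11 with only the groups compared.

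Genes called with H2O2 in WT, with H2O2 in the KD and in the interaction were 85, 25 and 45 with no filter, 97, 54 and 35 with DESeq2, 184, 470 (363 higher, 107 lower) and 141 without the 4 libraries, and 535, 804 and 261 with only the groups compared. The main fit pooled its spread over all 18 libraries. Among them are hnRNPM KD 3 and MagoHB KD 2, which stood apart and are in no H2O2 comparison. Without S100A16 KD untreated 1 alone, 3 genes were called with H2O2 in the KD. The main counts with H2O2 therefore depend on which libraries share the spread. Limma on all genes above 0 called 7 with H2O2 in the KD. The cause was not tested. At 5 CPM the covariances between KDs were 0.221 (S100A16 and hnRNPM), 0.211 (S100A16 and MagoHB) and 0.199 (hnRNPM and MagoHB), over fewer genes.

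Some values turned, and the cause was not tested. S100A14 in the untreated S100A16 KD was 0 with DESeq2 size factors and the DESeq2 test and -0.01 with no filter and with only the groups compared. S100A13 there was 0.17 by total counts and 0.16 in all 3 limma fits, and was called higher in each (adjusted p from 0.0223 to 0.0469; all alternatives to 0.785). Under H2O2, S100A14 was 0.09 by total counts and 0.02 with limma on all genes, and S100A13 was 0.16 by total counts, 0.01 at 5 CPM and 0.16 in the limma fits, called higher by total counts and limma (adjusted p from 0.0218 to 0.0468; all alternatives to 1). TXNRD1 in the interaction was -0.04 by total counts and in the limma fits, -0.01 at 5 CPM and with only the groups compared, and 0 with halved counts. MAGOH in the MagoHB KD was 0.08 by total counts and 0.07, 0.08 and 0.07 in the limma fits.

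With 1 library left out, genes called were 40 to 44 with H2O2 in WT, 3 to 7 with H2O2 in the KD (7 without S100A16 KD untreated 3) and 13 to 17 in the interaction (13 without WT untreated 3). The covariances ranged from 0.354 to 0.551, 0.346 to 0.587 and 0.324 to 0.552, lowest without hnRNPM KD 3, MagoHB KD 2 and MagoHB KD 2 and highest without WT untreated 1. S100A14 ranged from -0.17 to 0.16 in the untreated S100A16 KD and from -0.05 to 0.28 in the MagoHB KD, S100A13 from -0.10 to 0 under H2O2 and TXNRD1 from -0.01 to 0.04 in the interaction.

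Replicate numbers do not pair the libraries, and with them as a block 48, 11553, 4, 11653, 20, 10864 and 9986 genes were called in the order above. Of 229 values of named genes, 226 kept direction and call in that edgeR fit. LIF (adjusted p = 0.0622) and AMOTL2 (0.0606) with H2O2 in WT and LPCAT4 in the interaction (0.0993) lost their call. Transcript filters and transcript usage were not run, because the table holds genes. In the self-test, 1.5-fold changes were recovered in 52.2% of cases in the interaction and 80.6% to 98.5% elsewhere. This limits what these libraries show for small changes, most of all in the interaction. Only genes with a mean of at least 5 CPM were changed there, so recovery of weaker genes was not measured.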

Other observations

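The scan of 3' UTR words was chosen after the KD results were seen, as were the tests of line history and of UTR length and composition. The contrast with no shared WT libraries was fixed before the data were seen, and the limits for reading it after the result. Over 9642 genes and 16384 words of 7 bases, a different word led the falls in each KD. Genes with TCCTGGT in the 3' UTR were lower in the untreated S100A16 KD (log2 effect per word -0.201 ± 0.018, SE, z = -10.89), and TCCTGGT led again under H2O2 (-0.203, z = -11.1). TATATCT led in the hnRNPM KD (-0.291 ± 0.019, SE, z = -15.32) and CTTGAAA in the MagoHB KD (-0.247 ± 0.015, SE, z = -16.98). In the other untreated KDs the effects were 0.018 and 0.02 for TCCTGGT, 0.015 and 0.01 for TATATCT, and 0.004 and -0.008 for CTTGAAA. Of genes with the word, 42.7%, 47.9% and 50.2% fell in the 3 KDs, against 38.8%, 33.1% and 34.0% of genes without it, and the words held 1.22%, 2.38% and 2.9% of the variance. With shuffled fold changes the lowest z was -4.53, -4.29 and -4.43 in the S100A16, hnRNPM and MagoHB KDs. A word planted with an effect of -0.25 led in 20 of 20 trials in each. Words unlike the leading ones also passed the shuffled values, as did GACTGCA in the S100A16 KD (z = -8.19) and GTACCAC in the MagoHB KD (z = -8.18). Shuffling breaks any link of fold changes with UTR features, so it sets no floor for such links.

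A candidate explanation is seed matches of the RNA used for each knockdown, whose method is not given in the sources used here. The annotated mRNA of the targeted gene held its KD's word in 3 of 3 cases (S100A16 in 4 of 4 transcripts, HNRNPM in 3 of 3 and MAGOHB in 2 of 3), against 13.7%, 11.6% and 22.4% of genes of like length. The words also crossed over in 2 of 6 other pairs, S100A16 with CTTGAAA (2 of 4 transcripts) and MAGOHB with TCCTGGT (1 of 3). These mRNAs fell to 51.2% of WT in the MagoHB KD and to 65% in the untreated S100A16 KD. Falls also came without the KD's word, in HNRNPM in both of those KDs and in MAGOHB in the hnRNPM KD (44.4%). Whether a match lowered any of them was not tested. UTR length or base composition is argued against by a choice of the word in one random set of genes and its rank in the 4821 genes held out, with length and GC content in the model. The genes were split once, and each set served in turn for the choice. In all 6 such choices the KD's leading word was chosen, and it ranked 1 among the words of the same bases (held-out z from -13.33 to -7.26). The 6 are not independent, since a word that leads in both sets must rank 1 in each. The effect per word in coding sequence was 33.3 ± 9.0%, 59.8 ± 10.7% and 40.9 ± 7.3% of that in the 3' UTR (SE), which does not settle whether the word acts wherever it lies in the mRNA.

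The KDs moved many genes together against WT, though direct contrasts between pairs of KDs also called 9963 to 10931 genes. For the S100A16 KD with each other KD, the shared untreated WT libraries are argued against as the whole cause, since with none shared these 2 covariances were at least 84% of their values with shared controls. The hnRNPM and MagoHB pair could not be tested this way, since both KDs were measured untreated alone. A history of vector, selection or culture that the stable lines share and WT lacks could give the 3784 genes that moved one way in all 3 KDs, and cannot be told apart from effects of the targeted genes without a line carrying the vector alone.

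Changes with H2O2 were compared between WT and the S100A16 KD in fits to the groups compared. Of 535 genes called in WT, 365 (68.2%) had the same sign in the KD. Genes called in both numbered 21 higher (6.4 for independent lists), 32 lower (3.4) and 12 in opposite directions. Across 22382 genes the log2 changes had r = -0.000247. In the interaction, the word ATTTATT led the scan (-0.019, z = -5.56). The leading words with H2O2 were CTCTCTC in the KD (z = -5.0) and CAGCCAG in WT (z = -4.27). Shuffled fold changes were run only for the untreated KDs, so these z have no such reference.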
